A study of Mus musculus with 6 samples.

How the data were processed

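Total RNA of 6 cultures of mouse colonic fibroblasts was extracted on a Maxwell instrument, depleted of ribosomal RNA and made into directional libraries that were sequenced on an Illumina NextSeq, per the labels' protocols. The authors deposited a table of estimated counts per transcript, with 1 column per library and no scaling to a common total. Per the submitters' processing notes the estimated counts came from kallisto, with GRCm38 and mm10 as the genome builds. The kallisto version, its settings and any filter are not given in the sources used here. The table listed 120299 RefSeq transcripts of 38896 genes, and 99.99% of the accessions were matched to a RefSeq gene table of the GRCm38 build, from which gene identifiers, biotypes and coordinates were taken. The values behaved as estimates: 84.5 to 84.8% of the values above 0 in a library were not whole, at a tolerance of 1e-06. No mitochondrially encoded gene was listed, so the list of 13 such genes fixed beforehand could not be used. Because kallisto divides reads among transcripts by likelihood, reads of near-identical genes can be shared out wrongly, and such genes are named as uncertain. A pseudoalignment to transcripts also takes no account of reads from introns.

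The estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and compared between DSS and control by edgeR's quasi-likelihood test with the group alone as the term, with Benjamini-Hochberg adjustment over 19869 genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM factors. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The gene lists, 33 in all, were fixed before the data were examined, and the 30 with at least 5 tested members were tested by limma's camera on voom values with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fry's directional p tests whether the genes of a list move, on balance, one way, and compares the list with no other genes. Calls of fry are by this p unless its mixed p is named. The lists of neutrophil and mesothelial markers had too few tested members for a list test.

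The same 3 mice gave both groups, so libraries pair by animal, and the fit with the mouse as a block was among the alternatives fixed beforehand. Across genes, the deviations from the group means of the control and the DSS library of the same mouse correlated with r = 0.35, 0.21 and 0.46 in mice 1716, 1717 and 1718, against -0.36 to 0.02 for libraries of different mice. Genes are not independent replicates in this r. The common dispersion was 0.0196 without the block and 0.00649 with it. The correlation of log2 CPM between libraries was 0.985 to 0.989 within control, 0.983 to 0.986 within DSS and 0.961 to 0.975 between the groups. The first principal component held 54.9% of the variance and separated the groups, and the second held 19.1%. Pairs of libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 9.71 to 22.2, so no library appeared to be deposited more than once.

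Depth was 17293680 to 19482938 estimated counts per library. Protein-coding genes took 83.8 to 86.4% of these, and 3 ribosomal RNA entries that survived depletion took 7.69 to 9.14%, of which Rn28s1 took 5.06 to 6.41%. The tests were tested on simulated data drawn for the 19869 genes from the means, dispersions and library sizes of this comparison, in 1 draw per fit, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Without the block 25.4% of genes changed 1.5-fold, 71.6% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, and 7.1% of the 141 calls were false. With the block the shares were 59.7%, 94% and 97%, and 11.6% of the 189 calls were false. Both shares of false calls lay above the nominal 5%, in 1 draw each. The counts of either fit, those of the blocked one above all, may thus carry more false calls than the threshold states. The blocked draw kept the fitted effects of the mice. Both draws gave far fewer calls than the real comparison, so adjustment was stricter in them and the share recovered there may differ. A simulated list of 30 genes raised 1.5-fold was called by camera, and 0 of the other simulated lists. Genes were drawn independently, so this does not test camera where the genes of a list are correlated.

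Genes named in the text were chosen by a rule written before the data were examined: the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and the same direction in all 3 mice, a preset panel of 14 genes, and 2 to 4 members with the smallest p in each list described. Predicted genes and pseudogenes were passed over for the first part. Further genes, each stated as such, were named after their values were seen. Some genes that the rule selects are not reported here by name, and the counts of their lists include them. Alternatives fixed beforehand were the block, median-of-ratios (RLE) and upper-quartile scaling, DESeq2 with and without the block, limma-voom, no filter beyond 1 count and a filter of 50 counts in 3 libraries, transcripts in place of genes, glmTreat against a fold of 1.5, and leaving out each library and each mouse. Protein-coding genes alone, removal of the ribosomal RNA entries, a correction for GC content and transcript length with the block, and the estimated correlation or fry with the block were added after seeing the data. A GC value was found for 72.7% of the tested genes, under the 80% asked for, so the check is void for counts over all genes. It was used for lists, where 94.1 to 100% of the members had one, and for genes looked at singly. No sample was left out.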

Results

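RNA was sequenced from cultures of mouse colonic fibroblasts, the connective-tissue cells that support the epithelium of the large bowel. The cells came from the distal colon of mice aged 6 weeks and were grown for 2 passages before 24 h in control or inflammatory conditioned medium. The labels call the groups control and DSS, the usual abbreviation of dextran sulfate sodium, a chemical used to induce colitis in mice. The libraries labelled DSS were taken as the cultures in inflammatory medium, and how that medium was made is not given in the sources used here. Each of 3 mice, numbered 1716, 1717 and 1718, gave 1 control and 1 DSS library, so each group had n = 3 and the groups were paired by animal. The libraries held 19482938, 18552425 and 17734405 estimated counts in control and 17303371, 17931239 and 17293680 in DSS, in the order of the mouse numbers. Levels are counts scaled by library size (CPM) as mean ± SD, and changes are log2 fold changes of DSS against control ± SE. Of fits that left out data, "without control 1716" means without that 1 library and "without mouse 1716" means without both libraries of that animal. None of these fits used the mouse as a block, so they had fewer libraries and made no use of the pairing. A call lost in them need not depend on the library or animal left out.

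The series concerns primary cilia of the colon, inflammation and carcinogenesis, and the design poses a single comparison: what 24 h in inflammatory medium did to the transcripts of colonic fibroblasts. Higher in the DSS cultures by edgeR were 17 of 18 interferon-gamma-induced genes (GTPases but for Ido1 and Socs1), 22 of 38 type I interferon genes and 21 of 27 antigen presentation genes. So were 13 of 31 cytokines (1 fell) and 17 of 26 genes of the response to oxidants and metals (2 fell). Lower were 27 of 50 collagens and other matrix genes and 19 of 36 genes of hypoxia and glycolysis, with 1 that rose in each. Limma's camera, a test of whole lists, called each of these lists at a preset correlation between genes and none with an estimated correlation (adjusted p = 0.217 to 0.411, with an estimated correlation). Most genes that build the cilium did not pass the test, as was so for most genes tested, and the medians of their lists lay near 0. Of 19869 genes tested, 1465 were higher and 1174 lower in DSS by edgeR's quasi-likelihood test at an adjusted p under 0.05. All 2639 moved the same way in each of the 3 mice, which a call between 3 and 3 libraries makes likely in advance. Of the 2639 genes, 556 were more than 2-fold higher and 315 more than 2-fold lower. With the mouse as a block, which uses the pairing, 2447 genes were higher and 2518 lower, and this set held all 2639. The number of called genes was 1827 without mouse 1716, 649 without mouse 1717 and 664 without mouse 1718, and it was 1349 without control 1717 and 1494 without control 1718.

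The genes with the largest rises were Tgtp1, Serpina3f, Cxcl9, Gbp4, Iigp1, Gsta4, Tgtp2 and Cxcl10, with fitted log2 fold changes from 5.10 to 8.59. Tgtp1 (NCBI Gene 21822, chromosome 11, 48985329 to 48992246, GRCm38), which encodes an interferon-induced GTPase, went from 1.14 ± 0.751 to 434 ± 366 CPM (n = 3; edgeR adjusted p = 0.00326). Its near-identical neighbour Tgtp2 (NCBI Gene 100039796, chromosome 11, 49057196 to 49064212) rose by 5.35 ± 0.68, and reads can be split wrongly between the 2 copies, as between Gbp4, Iigp1, Serpina3f and their close relatives. Cxcl9 (NCBI Gene 17329, chromosome 5, 92321331 to 92328079), a chemokine that attracts T cells, went from 0.777 ± 0.0227 to 172 ± 117 CPM (log2 fold change 7.78 ± 0.77, edgeR adjusted p = 0.00168). Gsta4 (NCBI Gene 14860, chromosome 9, 78191966 to 78209349), a glutathione transferase that removes lipid peroxidation products, rose from 1.21 ± 0.100 to 56.5 ± 23.1 CPM. Serpina3f rose by 8.13 ± 0.93 and Iigp1 by 6.54 ± 0.88. With limma-voom in place of edgeR the adjusted p was 0.0607 for Serpina3f, 0.201 for Gbp4 and 0.0833 for Cxcl10. Gbp4 rose by 7.67 ± 1.23 (edgeR adjusted p = 0.00793), with 0.0593 without mouse 1716 and 0.0855 without mouse 1718. Cxcl10, a chemokine of the same receptor as Cxcl9, rose by 5.10 ± 0.88 (edgeR adjusted p = 0.0104), with 0.0507 without control 1717, 0.0721 without mouse 1716 and 0.102 without mouse 1718.

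The largest falls were those of Tnfsf18, Dio3, Trpa1, Aspn, Slc7a5, Trib3, Anxa8 and Col15a1. Tnfsf18 (NCBI Gene 240873, chromosome 1, 161494657 to 161505290), a ligand of the tumour necrosis factor family, fell from 10.1 ± 0.0294 to 0.171 ± 0.000444 CPM. On the log2 scale it fell by 5.83 ± 0.17, a value that rested on 9 counts over the DSS libraries (edgeR adjusted p = 3.76e-05). The DSS libraries held nearly the same level, so this SE is smaller than the counting noise of 9 counts, and the SE and p overstate the precision. Aspn (NCBI Gene 66695, chromosome 13, 49544443 to 49567565), a small proteoglycan that binds collagen, fell from 38.3 ± 3.58 to 4.51 ± 0.304 CPM (edgeR adjusted p = 6.8e-05). Slc7a5 (NCBI Gene 20539, chromosome 8, 121881146 to 121907686), a transporter of large neutral amino acids, fell from 111 ± 55.1 to 13.4 ± 0.807 CPM, and its edgeR adjusted p of 0.00343 became 0.064 without mouse 1717. Trib3, a pseudokinase induced by amino acid shortage, fell by 2.99, with edgeR adjusted p = 0.118 without mouse 1717 and 0.0624 without mouse 1718, and 0.0517 with limma-voom. Dio3, a deiodinase that inactivates thyroid hormone, fell by 3.15 (edgeR adjusted p = 0.12 without mouse 1717). Trpa1, an irritant-sensing ion channel, fell by 3.13 (0.065 without mouse 1718). Anxa8 fell by 2.84, with 0.0547 without mouse 1717 and 0.0624 without mouse 1718. Col15a1, a basement membrane collagen, fell from 317 ± 76.7 to 46 ± 26.4 CPM and lost its call without mouse 1717 (edgeR adjusted p = 0.104).

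**Figure D1:**
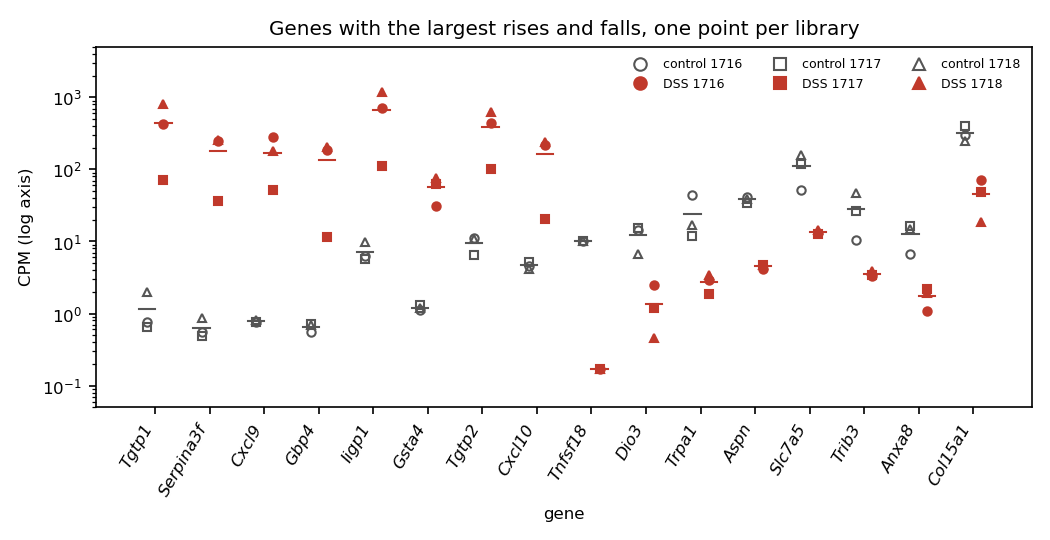
Level in each of the 6 libraries (CPM, log axis) of the 8 genes with the largest rises and the 8 with the largest falls, one point per library with the shape giving the mouse, and a bar at each group mean. For Tgtp1, Iigp1 and Cxcl10 the DSS library of mouse 1717 lies below those of the other mice, and for Tnfsf18 the 3 DSS points coincide at 0.171 CPM.

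Among the fixed lists, the interferon-gamma GTPase list had the largest median change. It holds interferon-gamma-induced GTPases, which act against intracellular pathogens, and also Ido1 and Socs1, which are not GTPases. Of its 18 genes tested 17 rose, and the list's median was 3.66. Of 38 genes of the type I interferon response 22 rose (median 1.13), and of 27 antigen presentation genes 21 rose (median 1.29). The other members of these lists did not pass. Adjusted over the list alone, 17, 30 and 23 members rose. Irgm1, a GTPase of this family, rose by 2.62 ± 0.34. Oas3, a sensor of double-stranded RNA, rose from 3.09 ± 0.666 to 12.7 ± 2.74 CPM, Zbp1 by 2.53 ± 0.33 and Bst2 by 1.44 ± 0.20. Among genes of peptide presentation by class I molecules, H2-D1 rose from 303 ± 22.2 to 796 ± 138 CPM, H2-K1 by 1.56 ± 0.18 and H2-T22 by 1.83 ± 0.13. B2m, the light chain they share, rose from 348 ± 16.2 to 850 ± 167 CPM (n = 3, edgeR adjusted p = 0.00241). H2 genes are close copies of one another, so their separate levels are uncertain. By limma's camera with a preset correlation of 0.01 the lists were higher than other genes. The adjusted p was 3.7e-10 for the GTPase list, 1.43e-13 for the type I response and 1.37e-12 for antigen presentation. Each call was lost when the correlation between genes was estimated from these libraries (adjusted p = 0.411 with an estimated correlation for all 3). The change was smaller in mouse 1717, where the median difference of the GTPase list was 2.05 against 4.40 in mouse 1716 and 3.96 in mouse 1718. Without mouse 1716, 10 genes of the GTPase list, 8 type I genes and 12 antigen presentation genes rose. Without mouse 1718 these counts were 5, 9 and 5. The type I count was 14 without control 1716 and 10 without control 1717. Over the same comparison the macrophage markers had a median of -0.34.

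Rises also outnumbered falls among cytokine and nuclear factor kappa B genes. Of 31 cytokines and chemokines 13 rose and 1 fell (median 1.09), and of 27 targets and feedback genes of nuclear factor kappa B, the transcription factor of inflammatory signalling, 16 rose and 1 fell (median 0.75). Adjusted over the list alone these counts were 20 and 1, and 21 and 2. Csf3, a growth factor for neutrophils, went from 2.96 ± 0.80 to 30.8 ± 12.2 CPM, Csf2 rose by 2.81 ± 0.31 and Ccl5, a chemokine for T cells and monocytes, by 1.82 ± 0.12. Il6 rose from 61.6 ± 8.80 to 232 ± 108 CPM (n = 3, edgeR adjusted p = 0.00938; 0.0961 without mouse 1718). Cxcl1, a chemokine for neutrophils, rose by 1.71 ± 0.31 (edgeR adjusted p = 0.012), with 0.0577 without control 1717, 0.147 without mouse 1717 and 0.0951 without mouse 1718. Ccl2 had a log2 fold change of 1.08 ± 0.33 and did not pass (edgeR adjusted p = 0.0752), but passed with the mouse as a block (0.00215) and without DSS 1716 (0.0312). Tnfaip3 and Nfkbiz, feedback regulators of this pathway, rose by 1.42 ± 0.13 and 0.66 ± 0.08, and Birc3, an inhibitor of apoptosis, by 0.96 ± 0.11. The members that fell were Cxcl12, by 0.74, and Tlr2, by 1.15 (both named after their values were seen). Cxcl12 lost its call without control 1716 or 1718, DSS 1717 or 1718, or mouse 1717 or 1718 (edgeR adjusted p = 0.0657 to 0.179), and Tlr2 without mouse 1717 (0.0769). Camera gave adjusted p = 1.55e-07 for the cytokines and 2.59e-09 for the nuclear factor kappa B list, against adjusted p = 0.217 and adjusted p = 0.354 with an estimated correlation. The cytokine count that rose was 22 with the block and 5 without mouse 1718. The nuclear factor kappa B count that rose was 7 without mouse 1717 and 4 without mouse 1718, and 2 fell with the block or without DSS 1716.

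In smaller inflammatory lists rises outnumbered falls, but most members did not pass. Of 20 acute phase and complement genes 9 rose, of 31 immediate early genes and targets of AP-1 and STAT3 10 rose, and of 16 genes of the prostaglandin pathway 4 rose. Adjusted over the list alone 10 acute phase genes rose and 1 fell, 13 immediate early genes rose and 3 fell, and 5 prostaglandin genes rose. Ptx3, a soluble pattern recognition molecule, went from 14.8 ± 2.67 to 40.3 ± 7.48 CPM. Saa3, an acute phase apolipoprotein, was at 508 ± 35.6 CPM in control and 697 ± 349 CPM in DSS and did not pass (edgeR adjusted p = 0.407). Fosl1, a subunit of AP-1, rose by 1.04 ± 0.15, with edgeR adjusted p = 0.0832 without mouse 1717 and 0.0541 without mouse 1718. The prostaglandin genes that rose were Ptges, which makes prostaglandin E2, from 139 ± 1.55 to 448 ± 89.8 CPM, Abcc4, a prostaglandin exporter, by 2.04 ± 0.23, the phospholipase Pla2g4a by 1.12 and the receptor Ptgfr by 0.84. Pla2g4a lost its call without mouse 1717 (0.0765) or mouse 1718 (0.102). Ptgfr, at 0.993 ± 0.108 CPM in control and 1.78 ± 0.333 CPM in DSS, lost its call in each of the 9 fits that left out a library or a mouse (edgeR adjusted p = 0.0567 to 0.231), with DESeq2 (0.158, and 0.29 with the block), with limma-voom (0.0565) and with no filter on low counts (0.0634). Ptgs2, the inducible cyclooxygenase, was at 1001 ± 169 CPM in control and 1519 ± 527 CPM in DSS and did not pass (edgeR adjusted p = 0.158), although it passed with the block (0.00646) and without DSS 1716 (0.0467). For the acute phase list camera gave adjusted p = 0.00339 (adjusted p = 0.411 with an estimated correlation) and 0.0303 for the immediate early list (adjusted p = 0.438 with an estimated correlation). For the prostaglandin list it gave 0.00319 (adjusted p = 0.411 with an estimated correlation). The immediate early call was lost without control 1716 (0.0753), control 1718 (0.0746), DSS 1717 (0.13) and mouse 1717 (0.082). The acute phase count that rose was at most 5 without any 1 control library, DSS 1716, DSS 1718, mouse 1716 or mouse 1718. The immediate early count that rose was at most 4 without any 1 control library, DSS 1717, DSS 1718, mouse 1717 or mouse 1718, and 1 fell without control 1716, DSS 1718 or mouse 1716. Of prostaglandin genes 2 rose without mouse 1717 and 2 without mouse 1718. With the block 7 prostaglandin genes rose and 1 fell, and 6 immediate early genes (3 by DESeq2) and 2 acute phase genes (1 by DESeq2) fell.

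Most tested genes of the response to oxidants and metals rose. Of 26 tested 17 rose and 2 fell, and adjusted over the list alone 22 rose and 2 fell (median 0.87). Txnrd1, a thioredoxin reductase, went from 276 ± 30.8 to 1127 ± 123 CPM, and Prdx1, a peroxidase that takes its electrons from thioredoxin, from 322 ± 40.7 to 2879 ± 720 CPM (n = 3, edgeR adjusted p = 0.000569). Gsr, which restores reduced glutathione, rose by 1.23 ± 0.08 and Taldo1, an enzyme of the pentose phosphate pathway, by 1.35 ± 0.08. The members that fell, named after their values were seen, were Gpx3, a secreted glutathione peroxidase, by 0.79, and the metal transporter Slc39a14, by 0.53. Slc39a14 lost its call without mouse 1717 (edgeR adjusted p = 0.0575) and mouse 1718 (0.0888). Camera gave adjusted p = 1.37e-12 for the list, and adjusted p = 0.411 with an estimated correlation. The count that rose was 9 without mouse 1717 and 11 without mouse 1718. The median difference was 0.79, 0.95 and 0.91 in mice 1716, 1717 and 1718.

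**Figure D2:**
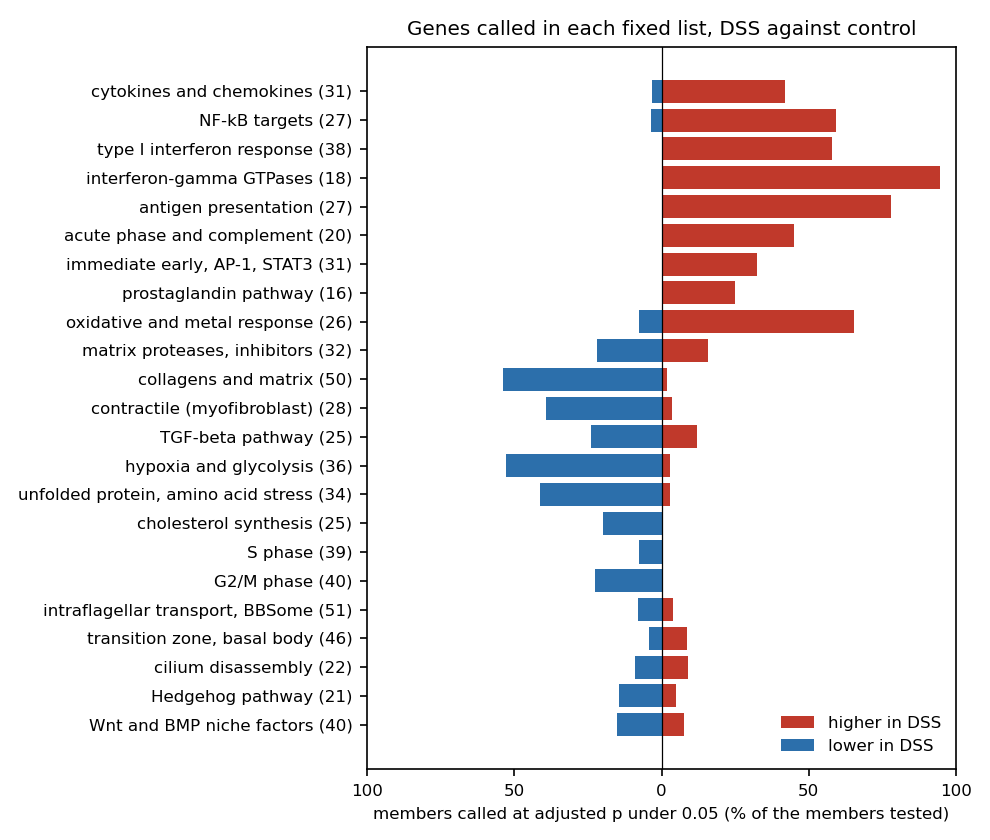
Share of the tested members of each list of biological processes (number tested in brackets) that were higher (red, to the right) or lower (blue, to the left) in DSS at an edgeR adjusted p under 0.05, in percent. The longest red bar is that of the interferon-gamma GTPase list, 17 of 18 (Ido1 and Socs1 included). The longest blue bars are those of collagens and matrix, 27 of 50, and of hypoxia and glycolysis, 19 of 36.

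Among matrix genes falls outnumbered rises. Of 50 collagens and fibrillar matrix genes 27 fell and 1 rose, and adjusted over the list alone 35 fell and 2 rose (median -0.64). Col1a1 (NCBI Gene 12842, chromosome 11, 94936224 to 94953042), which encodes a chain of type I collagen, fell from 17960 ± 1955 to 8605 ± 1176 CPM, with edgeR adjusted p = 0.00564, 0.113 without mouse 1717 and 0.0907 without mouse 1718. Col5a1 fell from 3363 ± 198 to 1407 ± 212 CPM, Col6a3 from 1528 ± 326 to 562 ± 25.9 CPM, and Ogn, a small proteoglycan, fell by 2.02 ± 0.16 on the log2 scale. Tnxb, the member that rose, went from 11.2 ± 1.93 to 28.6 ± 4.92 CPM and was named after its value was seen. Of 28 contractile genes of myofibroblasts, the fibroblasts that pull on matrix, 11 fell and 1 rose, and adjusted over the list alone 12 fell and 2 rose (median -0.21). Acta2, smooth muscle actin, fell from 1560 ± 33.5 to 844 ± 103 CPM (edgeR adjusted p = 0.00269; 0.0611 without mouse 1717), and Tpm2, a tropomyosin, from 242 ± 20.8 to 140 ± 4.23 CPM. Cnn1 fell by 0.78 ± 0.10. The member that rose was Myh11, a smooth muscle myosin, by 0.43 ± 0.10, a call lost without control 1716 or 1717, DSS 1717 or 1718, or mouse 1717 or 1718 (edgeR adjusted p = 0.0823 to 0.254). For collagens camera gave adjusted p = 1.61e-15 (adjusted p = 0.217 with an estimated correlation) and 7.77e-05 for contractile genes (adjusted p = 0.411 with an estimated correlation). Without mouse 1717 and without mouse 1718, 7 and 11 matrix genes fell, and 3 and 4 contractile genes. Without control 1717, 7 contractile genes fell. In both lists 2 members rose with the block, without DSS 1716 and without mouse 1716. Beside these, the median was -0.34 for macrophage markers and -0.31 for fibroblast markers.

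Proteases and their inhibitors moved in both directions. Of 32 tested, 5 rose and 7 fell, and adjusted over the list alone 7 rose and 10 fell. The median log2 fold change was -0.18 and the mean 0.03. Camera placed the list lower but did not call it (adjusted p = 0.129), except without DSS 1717 (0.0321) and without mouse 1717 (0.0318). The members that rose were Mmp3, Mmp13, Mmp10, Mmp8 and Adamts9, proteases that act on collagens and proteoglycans. Mmp3 went from 347 ± 81 to 1640 ± 244 CPM (n = 3, edgeR adjusted p = 0.000959) and Mmp13 from 208 ± 78.3 to 957 ± 180 CPM. Timp3, an inhibitor of such proteases, fell from 443 ± 25.5 to 152 ± 13 CPM. The proteases Adamts12 and Adam12 fell by 1.24 ± 0.11 and fell by 1.18 ± 0.14. Mmp13 lost its call without mouse 1717 (0.0616), Mmp10 without mouse 1717 (0.0903) and mouse 1718 (0.0798), and Adamts9 without control 1717 or 1718 or mouse 1717 or 1718 (edgeR adjusted p = 0.0542 to 0.155). Mmp8, also a neutrophil marker, lost its call without control 1716 or 1718, DSS 1717 or 1718, or any 1 mouse (edgeR adjusted p = 0.0562 to 0.142). With the block 8 rose and 13 fell. The count that rose was 3 without control 1718, 1 without mouse 1717 and 2 without mouse 1718. The count that fell was 3 or 4 without any 1 control library, DSS 1718, mouse 1716 or mouse 1717. Mmp10, Mmp13 and Adamts9 were named after their values were seen.

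Of 25 genes of the transforming growth factor beta pathway, a driver of matrix production, 3 rose and 6 fell, and adjusted over the list alone 5 rose and 8 fell (median -0.11). Pmepa1, a feedback inhibitor, fell from 419 ± 56.1 to 188 ± 2.42 CPM and the receptor Tgfbr2 from 400 ± 46.2 to 216 ± 14.5 CPM. The members that rose were Id3, by 1.53 ± 0.19, Tgif1, by 0.64 ± 0.08, and Tgfbr3, by 0.55 ± 0.12. Tgif1 lost its call without mouse 1717 (edgeR adjusted p = 0.0527). Tgfbr3, named after its value was seen, lost it without control 1717 or 1718, DSS 1717 or 1718, or mouse 1717 or 1718 (edgeR adjusted p = 0.0696 to 0.189). Camera did not call the list (adjusted p = 0.158). By limma's fry, which tests whether a list's genes move on balance one way and compares them with no other genes, adjusted p = 0.00833, and 0.0417 with the block. Camera with an estimated correlation did not call the list either (adjusted p = 0.411, and 0.409 with the block). With the block 6 rose and 10 fell (3 and 8 by DESeq2), and without mouse 1717 1 rose and 2 fell.

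Metabolic and stress lists held more falls than rises. Of 36 genes of hypoxia and glycolysis 19 fell and 1 rose, and adjusted over the list alone 20 fell and 1 rose (median -0.49). Pfkfb3, which makes the activator of phosphofructokinase, fell from 212 ± 7.93 to 108 ± 7.69 CPM, and P4ha1, a hydroxylase needed for collagen folding, from 349 ± 34.1 to 192 ± 3.80 CPM. Egln1, an oxygen sensor, fell by 1.12 ± 0.12. The member that rose, Adm, went from 82.5 ± 23 to 166 ± 31.2 CPM and was named after its value was seen. It lost its call without control 1717 or 1718, DSS 1716 or 1718, or mouse 1717 or 1718 (edgeR adjusted p = 0.0534 to 0.171). Of 34 genes of the unfolded protein and amino acid stress responses 14 fell and 1 rose, and adjusted over the list alone 15 fell and 4 rose (median -0.17). Shmt2, an enzyme of serine and folate metabolism, fell from 77.4 ± 17.1 to 25.3 ± 1.65 CPM, Phgdh, the first enzyme of serine synthesis, from 52.8 ± 16 to 13.1 ± 1.31 CPM, and Asns, which makes asparagine, from 110 ± 39.8 to 30.3 ± 3.36 CPM. Mthfd2 fell by 2.07. Without mouse 1717 the edgeR adjusted p was 0.0507 for Phgdh, 0.0754 for Mthfd2 and 0.0844 for Asns, and for Asns it was 0.0558 without mouse 1718. Slc7a11, a cystine importer that also serves glutathione synthesis, was the member that rose, from 160 ± 18.4 to 685 ± 230 CPM. Hspa5, a chaperone of the endoplasmic reticulum induced by unfolded protein, was at 516 ± 95.2 CPM in control and 549 ± 32.9 CPM in DSS and did not pass (edgeR adjusted p = 0.721). Mthfd2, Asns and Hspa5 were named after their values were seen. For hypoxia and glycolysis camera gave adjusted p = 1.17e-11 (adjusted p = 0.411 with an estimated correlation) and 0.0023 for the stress list (adjusted p = 0.556 with an estimated correlation). Of the hypoxia list 12 fell without control 1717, 5 without mouse 1717 and 8 without mouse 1718. Of the stress list 8 fell without control 1717, 9 without DSS 1717, 1 without mouse 1717 and 4 without mouse 1718. With the block 5 members of the stress list rose.

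Of 25 genes of cholesterol synthesis and uptake 5 fell and the others did not pass, and adjusted over the list alone 8 fell (median -0.20). Among those that fell were Cyp51, Hmgcs1 and Fdps, enzymes of this synthesis, the last named after its value was seen. Cyp51 fell from 49.7 ± 2.65 to 32.5 ± 3.49 CPM. Without mouse 1717 the edgeR adjusted p was 0.0755 for Cyp51, 0.172 for Hmgcs1 and 0.205 for Fdps. Hmgcs1 also lost its call without control 1716 or 1717, DSS 1716 or 1717, or mouse 1716 (0.054 to 0.0972), and Fdps in every fit that left out data except that without DSS 1718 (0.0818 to 0.205), with no filter on low counts (0.0624) and with DESeq2 and the block (0.0555). Camera gave adjusted p = 0.00244 (adjusted p = 0.438 with an estimated correlation) and 0.114 without mouse 1716. The count that fell was at most 3 without control 1716 or 1717, DSS 1716 or 1717, or any 1 mouse, and with the block 9 fell and 1 rose by edgeR, against 5 that fell by DESeq2.

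Both cell cycle lists had medians below 0, but few genes passed alone. Of 40 genes of G2 and M phase 9 fell (median of the list -0.76), and of 39 genes of S phase 3 fell (median -0.48). Adjusted over the list alone 24 and 2 fell. Ccnb2, a mitotic cyclin, fell from 27.3 ± 2.39 to 13.3 ± 2.98 CPM, and Kif20a, a motor of cell division, from 60.8 ± 9.63 to 29.9 ± 7.71 CPM. The S phase genes that fell were Ccne1, a cyclin of S phase entry, from 12.9 ± 0.835 to 8.08 ± 0.213 CPM, Dut from 18.6 ± 1.93 to 11.5 ± 0.781 CPM and Tipin from 11.3 ± 0.789 to 8.16 ± 0.961 CPM. Mki67, a marker of cycling cells, was at 259 ± 76.5 CPM in control and 145 ± 71.6 CPM in DSS and did not pass (edgeR adjusted p = 0.163). It passed with the mouse as a block (0.000842), without DSS 1716 (0.0196) and without mouse 1716 (0.0165). With the block 39 genes of G2 and M phase and 24 of S phase fell, against 37 and 17 by DESeq2. Camera gave adjusted p = 6.81e-13 and 1.95e-06, against adjusted p = 0.438 with an estimated correlation for both. Without DSS 1716 or mouse 1716, 35 genes of G2 and M phase fell, against at most 3 without control 1716 or 1717, DSS 1717 or 1718, or mouse 1717 or 1718. Of S phase 8 fell without DSS 1716 and 7 without mouse 1716. Without mouse 1717 the edgeR adjusted p was 0.0912 for Ccnb2, 0.141 for Kif20a, 0.0602 for Ccne1 and 0.0594 for Dut, and without mouse 1718 it was 0.055, 0.0582, 0.068 and 0.0588. Tipin lost its call in all fits that left out data except that without DSS 1716 (edgeR adjusted p = 0.0719 to 0.215), with no filter on low counts (0.054) and with DESeq2 and the block (0.0791).

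Genes of the primary cilium, the sensory organelle the series is about, mostly did not pass. The same was so of genes at large, of which 2639 of 19869 passed. Of 51 genes of intraflagellar transport and the BBSome, which carry cargo along the cilium, 2 rose and 4 fell (median -0.05), and of 46 genes of the transition zone and basal body at its base 4 rose and 2 fell (median -0.07). Of 22 genes linked to cilium disassembly 2 rose and 2 fell (median -0.12). Adjusted over the list alone these counts were 2 and 4, 4 and 2, and 2 and 4. Ift88 (NCBI Gene 21821, chromosome 14, 57424064 to 57517936), a core transport subunit, was at 9.06 ± 0.489 CPM in control and 8.06 ± 1.11 CPM in DSS (n = 3, log2 fold change -0.17 ± 0.13, edgeR adjusted p = 0.456). Kif3a, a motor subunit, had a log2 fold change of -0.06 ± 0.07 (edgeR adjusted p = 0.646) and Arl13b, a GTPase of the ciliary membrane, of -0.18 ± 0.09 (0.257). These values do not show that the levels were equal, but for each of these genes a 1.5-fold change lay more than 2 SE away. Other members that did not pass need not be unchanged: in simulated data of this design 25.4% of genes changed 1.5-fold were recovered. That draw gave 141 calls against 2639 in the real comparison, so its adjusted p was harder to pass and real recovery may be higher. Rab3ip, an activator of the Rab proteins that start cilium assembly, rose from 15.3 ± 0.842 to 32.5 ± 2.28 CPM (edgeR adjusted p = 0.000853) and kept its call in each of the 9 fits that left out a library or a mouse. Of the transport list Bbs12 rose by 0.43 ± 0.10 and Tulp3 by 0.28 ± 0.07, while Ift20 and Rab23 fell by 0.53 and fell by 0.49, and Ttc8 and Kif3b fell by 0.48 and fell by 0.27. Of the transition zone list Fbf1, Rab11a and Ofd1 also rose, by 0.45, 0.36 and 0.46, and Anks6 fell by 0.43. Of the disassembly list Dynlt1b and Kif2a rose by 0.89 and 0.68, Septin7 fell by 0.40 and Aurka fell by 0.82. Bbs12, Tulp3, Ofd1 and Anks6 were named after their values were seen. Apart from Rab3ip, each of these calls was lost without mouse 1717 and without mouse 1718, with edgeR adjusted p from 0.0548 (Dynlt1b) to 0.293 (Anks6) and from 0.0558 (Dynlt1b) to 0.204 (Bbs12).

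Single libraries moved the ciliary counts too. Of the transport list at most 2 genes fell without any 1 control library, DSS 1717 or DSS 1718, and Bbs12 and Tulp3 lost their calls in these 5 fits and without mouse 1716 (edgeR adjusted p = 0.0592 to 0.145). Without control 1717, 2 genes of the transition zone list rose. In the same list 1 gene fell without control 1717, control 1718, DSS 1716 or DSS 1717, where the call of Anks6 was lost (edgeR adjusted p = 0.104 to 0.14). Anks6 also lost its call without DSS 1718 (0.0686) and mouse 1716 (0.0663), and without mouse 1716 edgeR called 0 genes of the list lower (7 at an unadjusted p under 0.05). Of the disassembly list 7 genes fell without DSS 1716 and 6 without mouse 1716, against 1 without any other single library. This list shares a member with that of G2 and M phase, of which 35 genes fell without DSS 1716 or mouse 1716. Falls in the disassembly list thus need not concern the cilium. With the block 9 disassembly and 6 transition zone genes fell by edgeR, against 5 and 1 by DESeq2, and 5 transport genes fell and 3 rose by edgeR, against 2 and 0 by DESeq2 (6 and 3 at an unadjusted p under 0.05). Camera called none of the 3 lists, with adjusted p = 0.128, 0.491 and 0.128, except the disassembly list without DSS 1716 (0.0333). Fry's directional p called none of them without the block (adjusted p = 0.0849, 0.924 and 0.166). With the block it called the transport and the disassembly list lower (0.0268 for each), and not the transition zone list (0.682). Fry's mixed p, which tests for changes in either direction, called all 3 without the block (adjusted p = 0.000312, 4.91e-08 and 0.00103). It compares a list with no other genes, and it also called the endothelial markers (3.79e-06). Camera with an estimated correlation called neither the transport nor the disassembly list (adjusted p = 0.427 and 0.438, and 0.409 for each with the block). Another test, filter or scaling also ended the calls of Ttc8, Kif3b, Bbs12, Tulp3, Anks6 and Aurka, with adjusted p = 0.0508 (Anks6, protein-coding genes only in edgeR) to 0.0836 (Ttc8, DESeq2 with the block). At an unadjusted p under 0.05 edgeR counted 13 of 51 transport, 16 of 46 transition zone and 11 of 22 disassembly genes, against 5672 of all 19869 genes.

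Of 21 genes of the Hedgehog pathway, which signals through the cilium, 1 rose and 3 fell, and adjusted over the list alone 1 rose and 3 fell (median -0.15). Gli1, a transcriptional target used as its readout, fell from 1.27 ± 0.27 to 0.303 ± 0.199 CPM (n = 3, edgeR adjusted p = 0.02), a call lost without control 1716 or 1718, DSS 1718, mouse 1716 or mouse 1718 (0.0612 to 0.144). Gli3 fell by 0.46 and the co-receptor Cdon fell by 1.10, while Foxf1, a target in gut mesenchyme, rose by 0.44. Ptch1, a receptor that is itself a target, was at 62.2 ± 5.39 CPM in control and 64.3 ± 5.89 CPM in DSS and did not pass (edgeR adjusted p = 0.794). Gli3 lost its call without mouse 1717 (0.0699) and mouse 1718 (0.057), Cdon without control 1717 or 1718, DSS 1718, mouse 1717 or mouse 1718 (0.0527 to 0.135), and Foxf1 without control or DSS 1717 or 1718 or mouse 1717 or 1718 (0.0551 to 0.139). Camera placed the list lower with adjusted p = 0.0189, against adjusted p = 0.438 with an estimated correlation. That call was lost without control 1716 (0.0753), control 1718 (0.0746), DSS 1717 (0.0587) and mouse 1716 (0.106). At most 1 gene fell without control 1718, DSS 1718, mouse 1717 or mouse 1718, and 6 fell with the block (3 by DESeq2).

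Of 40 Wnt, bone morphogenetic protein and growth factor genes through which fibroblasts act on epithelial stem cells, 3 rose and 6 fell, and adjusted over the list alone 3 rose and 8 fell (median -0.19). Bmp6 rose from 5.91 ± 1.21 to 31.1 ± 6.55 CPM (n = 3, edgeR adjusted p = 0.00097), and Ereg and Fgf7, growth factors for epithelium, by 1.21 ± 0.25 and 1.17 ± 0.20. The Wnt antagonists Dkk2 and Sfrp4 fell by 1.90 ± 0.24 and fell by 2.58 ± 0.38. Without mouse 1717 the edgeR adjusted p was 0.122 for Ereg, 0.132 for Fgf7, 0.0507 for Dkk2 and 0.0594 for Sfrp4, and without mouse 1718 it was 0.158 for Ereg, 0.0747 for Fgf7 and 0.0548 for Sfrp4. Ereg also lost its call without control 1718, DSS 1717 or DSS 1718 (edgeR adjusted p = 0.0528 to 0.0695) and Fgf7 without control 1717 (0.0504). Ereg and Fgf7 were named after their values were seen. Camera did not call the list (adjusted p = 0.196). Without control 1716, DSS 1716 and mouse 1716 the count that rose was 5, 5 and 7. Without mouse 1717 1 rose and 1 fell, and without mouse 1718 1 rose and 3 fell.

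**Figure D3:**
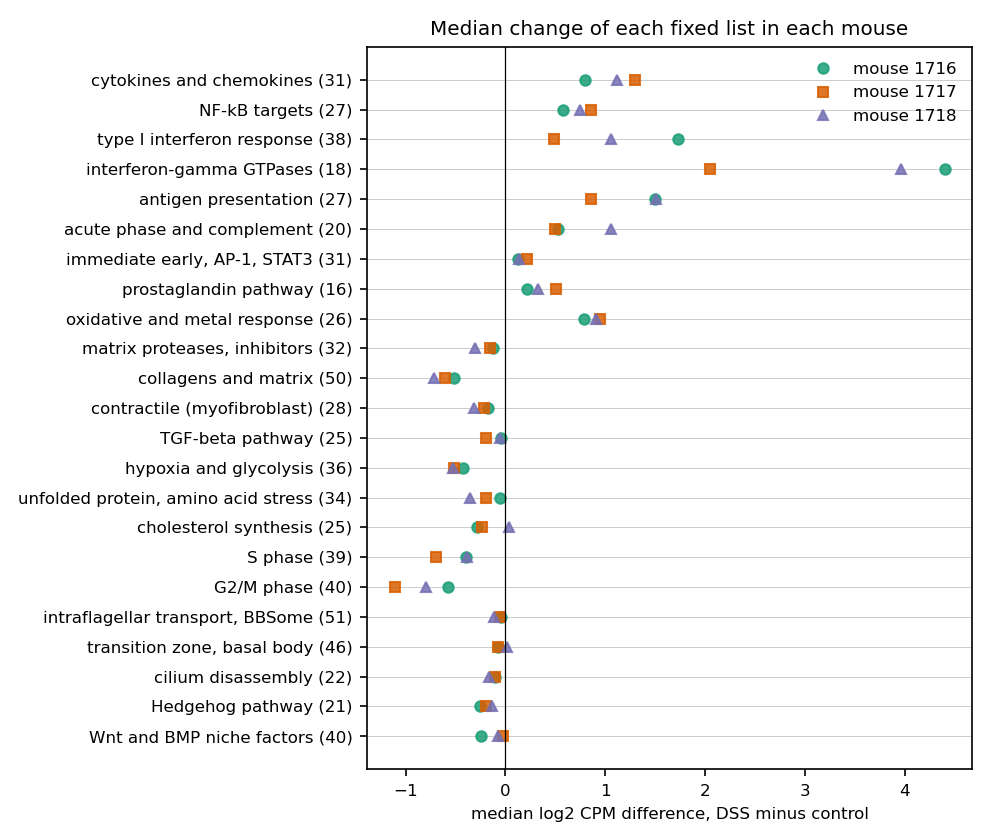
Median over each list (number tested in brackets) of the log2 CPM difference of DSS minus control, one point per mouse. The interferon-gamma GTPase list (Ido1 and Socs1 included) lies at 4.40, 2.05 and 3.96 in mice 1716, 1717 and 1718. The cytokines lie at 0.80, 1.30 and 1.12, and the transport genes of the cilium at -0.04, -0.05 and -0.11.

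Markers of other cell types described what else the cultures held. Of 21 fibroblast markers 3 rose and 6 fell, and adjusted over the list alone 4 rose and 8 fell (median -0.31). Those that fell included the collagens Col1a1, Col1a2 and Col3a1, which also stand in the matrix list, and those that rose, named after their values were seen, were Pdgfra, by 0.71, Twist2, by 0.85, and Ackr4, by 1.78. Col1a2 and Col3a1 lost their calls without mouse 1717 (edgeR adjusted p = 0.14 and 0.111) and mouse 1718 (0.129 and 0.0869). Pdgfra, Twist2 and Ackr4 all lost theirs without control 1717, control 1718 or mouse 1718, and in up to 3 further fits that left out data (edgeR adjusted p = 0.0506 to 0.155). Without control 1717 3 fibroblast markers fell, without mouse 1718 1 fell, without mouse 1717 edgeR called 0 lower (10 at an unadjusted p under 0.05), and with the block 5 rose. Camera did not call this list (adjusted p = 0.0703), except with no filter on low counts (0.019), without DSS 1717 (0.0171) and without mouse 1717 (0.0318). Of 21 macrophage markers 2 rose and 7 fell (median -0.34), and adjusted over the list alone 2 rose and 9 fell. Lyz2, lysozyme, fell from 1359 ± 324 to 711 ± 197 CPM and C1qc, a complement subunit made by macrophages, from 48 ± 4.24 to 24 ± 4.48 CPM. Fcgr1, a receptor for antibodies, fell by 1.20 ± 0.13, while Itgax and Cd68 rose by 1.55 ± 0.17 and 0.71 ± 0.14. Lyz2, named after its value was seen, lost its call in all fits that left out data except those without control 1716 or DSS 1717 (edgeR adjusted p = 0.0525 to 0.238). Cd68, likewise named, lost it without mouse 1717 (0.0838) and mouse 1718 (0.0834). For macrophage markers camera gave adjusted p = 0.00244, against adjusted p = 0.438 with an estimated correlation. With the block 12 macrophage markers fell, and 3 fell without control 1717, 3 without mouse 1717 and 4 without mouse 1718.

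Of 15 markers of smooth muscle, pericytes and interstitial cells 3 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose. They were Actg2, Cnn1 and Myh11, which the contractile list also holds, and Notch3, which fell by 0.57 and lost its call without control 1717 or 1718, DSS 1716 or 1718, or any 1 mouse (edgeR adjusted p = 0.0507 to 0.174). Camera gave adjusted p = 0.0121 (adjusted p = 0.427 with an estimated correlation), with 0.0571 without control 1716 and 0.118 without mouse 1716, and 8 fell with the block. Of 10 markers of glia and neurons Uchl1 rose by 1.14 and Ret fell by 1.69, with the same counts when adjusted over the list alone. With the block 5 fell and camera called the list (adjusted p = 0.0198, against 0.213 without the block), as it did without control 1718 (0.0295) and without DSS 1716 (0.0248). With an estimated correlation the list was not called (adjusted p = 0.632, and 0.427 with the block). Sox10, a glial transcription factor named after its value was seen, was at 61.6 ± 30.6 CPM in control and 60.7 ± 40.2 CPM in DSS and did not pass (n = 3, edgeR adjusted p = 0.985). Uchl1 lost its call without DSS 1717 or 1718 or mouse 1717 or 1718 (edgeR adjusted p = 0.0546 to 0.126), and Ret without mouse 1717 (0.0518).

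Of 7 epithelial markers tested Muc2, a goblet cell mucin, fell from 9.17 ± 2.13 to 2.12 ± 0.569 CPM. Krt19, also a mesothelial marker, fell by 1.61 ± 0.28, a call lost without mouse 1716 (edgeR adjusted p = 0.0631) and mouse 1718 (0.0743). The 7 epithelial markers summed to 18.2 CPM in control and 10.5 CPM in DSS, and adjusted over the list alone 2 fell. Of 16 endothelial markers Esam and Prox1 rose by 1.75 and 0.67 and Erg fell by 1.30, and adjusted over the list alone 2 rose and 3 fell, as many as with the block. Esam lost its call without mouse 1716 (edgeR adjusted p = 0.055), Prox1 without control 1716 or 1718 or any 1 mouse (0.0515 to 0.127) and Erg without control 1716 or 1717, DSS 1716 or 1718, or any 1 mouse (0.0842 to 0.182), and with DESeq2 and the block the adjusted p was 0.121 for Prox1 and 0.101 for Erg. Camera called neither the epithelial (adjusted p = 0.232) nor the endothelial list (0.583). Of 4 neutrophil markers tested Mmp8 rose, and 2 rose without DSS 1716. Of 4 mesothelial markers Krt19 fell. Of 5 lymphocyte and mast cell markers edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05, and camera gave adjusted p = 0.408. Their sum was 9.11 CPM in control and 10.2 CPM in DSS.

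By camera 19 of the 30 lists tested were called, 9 higher and 10 lower. With an estimated correlation camera called 0 of them, with 3 at an unadjusted p under 0.05. Fry called 9 of the 30, of which 8 were among the 19, and with the block 15, of which 11 were.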

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

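The protein-coding, ribosomal RNA and GC alternatives and the block with an estimated correlation or with fry were chosen after seeing the data. The count of 2639 called genes stayed within 1.5 times under RLE (2626) and upper-quartile scaling (2603), DESeq2 (2722; 3039 with the block), limma-voom (2528), no filter (2394), the strict filter (2628), protein-coding genes alone (2410) and removal of ribosomal RNA entries (2638). With the mouse as a replicate block 4965 genes were called, 2447 higher and 2518 lower, and the share of false calls in simulated data was 11.6%, against 7.1% without it. Transcripts in place of genes gave 337 calls of 48402, 184 higher and 153 lower, in 301 genes, of which 272 were called as genes; counts divided over more features leave fewer in each. A test against a fold of 1.5 gave 457, 309 higher and 148 lower, and so 67.6% higher against 55.5%. Leaving out 1 library or mouse gave 649 to 2418 called genes, 378 to 1310 higher and 185 to 1108 lower. Fewer libraries were fitted in each, without the block, so differences between mice stayed in the spread. Why the counts were lowest without mouse 1717 and mouse 1718 was not tested. Without mouse 1717 the share of called genes that were higher was 71.5%.

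Camera called 19 of 30 lists, but with an estimated correlation 0 (3 at an unadjusted p under 0.05), and 0 with that and the replicate block (1 at an unadjusted p under 0.05). Over the 30 lists the adjusted p with an estimated correlation ran from 0.217 to 0.742 (0.217 to 0.556 over the 19), and with the block from 0.409 to 0.602. Fry called 9 lists, 8 of them among the 19, and with the replicate block 15, 11 of them among the 19; the other 4 were the lists of ciliary transport, cilium disassembly, transforming growth factor beta and epithelial markers. At the preset correlation camera called 20 lists with the block, 19 with RLE scaling, 20 with no filter and 16 to 21 when a library or mouse was left out. The block added the list of glia and neurons (adjusted p = 0.0198) and changed no other list call of camera. With GC content and length corrected in the blocked fit the same list was added (0.0391). For 194 genes looked at singly 3865 alternative values were computed, those with the GC and length correction among them. Of the 3865 values 3481 kept the side of the threshold, 357 lost the call and 27 gained it. Among genes called in either fit 0 values changed direction, and direction was not compared where neither fit called the gene. With the block 7 of the 194 genes gained a call, among them Ccl2, Ptgs2 and Mki67, and 0 lost it. At this depth 25.4% of simulated 1.5-fold changes and 71.6% of 2-fold changes were recovered, against 59.7% and 94% with the replicate block at the same depth. These draws gave 141 and 189 calls against 2639 and 4965 in the real fits, so adjustment was stricter in them and real recovery may be higher. Depth itself was not varied.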

Other observations

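The tests of fibroblast share, of a weaker response of the whole culture, of one strength of response and of macrophage share were chosen after the result was seen, as were the gene families and the genes named here outside the lists. The rule for the tests of a weaker response and of one strength was also revised after outcomes were seen, so as to weigh the median against the spread of the members, and a stricter rule tried before, that both quartiles lie at or above 0, left both explanations open. The test of fibroblast share replaced one on the macrophage median alone (-0.34, quartiles -0.94 and 0.01), which left that explanation open once the spread was weighed. The genes in this and the next paragraph were picked from the largest changes outside all lists at a mean of at least 20 CPM, predicted genes passed over, and were not tested as groups. Gsta3, a glutathione transferase, went from 2.29 ± 0.831 to 37.9 ± 17 CPM, Gstm1 from 22.9 ± 1.91 to 106 ± 36.8 CPM, and Abcc1, which exports glutathione conjugates, from 326 ± 34.5 to 1059 ± 232 CPM (n = 3 in each group). Prdx6, a peroxiredoxin, rose by 2.22 ± 0.27, with edgeR adjusted p = 0.00292 and 0.0517 without mouse 1718. Heph, a copper enzyme that oxidises iron, rose from 5.28 ± 2.52 to 128 ± 39.9 CPM, Procr, the endothelial protein C receptor, from 41.9 ± 9.83 to 476 ± 251 CPM, and Cemip, which takes part in breaking down hyaluronan, from 73.6 ± 24.3 to 550 ± 161 CPM. Has2, which makes hyaluronan, fell from 175 ± 14.2 to 57.4 ± 3.92 CPM, and Vcan, a proteoglycan that binds it, from 752 ± 167 to 288 ± 65.4 CPM. Gsta and Gstm genes are close copies, so the level of each is uncertain.

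Among the falls, Aldh1l2, an enzyme of mitochondrial folate metabolism, fell from 112 ± 36.2 to 18 ± 2.23 CPM, Aldh18a1, of proline synthesis, by 1.46 ± 0.17, and the arginine transporter Slc7a1 fell by 1.42 ± 0.21. Pck2 fell by 1.24 ± 0.24. Without mouse 1717 the edgeR adjusted p was 0.0519 for Aldh18a1, 0.0903 for Slc7a1 and 0.164 for Pck2, and Pck2 also lost its call without control 1717, DSS 1717, DSS 1718 and mouse 1718 (0.05 to 0.125). Ccn4 fell from 396 ± 55.3 to 91.2 ± 23.5 CPM, Npr3 from 297 ± 80.6 to 63.4 ± 19.2 CPM, Nrep from 149 ± 35.8 to 29 ± 5.92 CPM and Cd248 from 118 ± 20.9 to 46.5 ± 5.77 CPM. Ncam1 fell from 276 ± 13.2 to 67.2 ± 25 CPM, with edgeR adjusted p = 0.0595 without mouse 1717. Of 241 families of genes with a shared symbol stem and at least 8 tested members, camera called 11, and with an estimated correlation 0 (lowest adjusted p = 0.96, and 6 families at an unadjusted p under 0.05). Among those called outside the fixed lists were the protocadherin beta cluster, lower with a median of -0.38 over 18 members, and the aldo-keto reductases, higher with a median of 0.28 over 11. Most members did not pass alone: edgeR called 3 of the 18 lower and 3 of the 11 higher.

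Of 50 collagens and matrix genes 27 fell and 1 rose by edgeR, and camera called the list lower, but not with an estimated correlation (adjusted p = 0.217, and 0.409 with the block). In the blocked fit the median of the list was -0.63 before and -0.61 after the trends with GC content and transcript length were removed, and 38 members were still called lower, which argues against those trends as the cause. A lower share of fibroblasts alone would raise the markers of other cell types alike. Smooth muscle was left out because myofibroblasts express its markers. Of 66 such markers 11 from 5 types fell and 6 rose (6 fell without control 1717, 5 without mouse 1717 and 6 without mouse 1718). Of the 11, 7 were markers of macrophages, cells that may have changed state, and Krt19 counted for both epithelium and mesothelium. The 5 types thus rest on few genes outside macrophages, and 3 types had a fall when any 1 mouse was left out. The medians were -0.34 for macrophages, -0.48 for glia and neurons, -0.33 for mesothelium, -0.26 for epithelium, -0.20 for endothelium, 0.16 for lymphocytes and mast cells and 0.63 for neutrophils, and -0.57 for smooth muscle. A change within the fibroblasts stays open as a hypothesis found and tested on the same data, as does a lower share of them as a part of the cause.

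In the DSS culture of mouse 1717 the genes of the interferon-gamma GTPase list rose less. The gene-wise difference of this mouse's change from the mean of the other mice had a median of -2.10 and was below 0 for 18 of 18 genes. The type I interferon genes (median -0.74, 37 of 38 lower) and antigen presentation genes (-0.76, 25 of 27) went the same way. Mouse 1717 was picked for the smallest median of the GTPase list, so a difference below 0 there was likely in advance. The estimated correlation between genes was 0.946, 0.69 and 0.675 in these lists, so the counts of genes are not independent and describe 1 animal. Cell cycle genes also set this mouse apart, with a larger fall (-0.36 and 38 of 40 lower for G2 and M phase, -0.26 and 31 of 39 for S phase). A weaker response of the whole culture was assumed to scale the oxidant and metal list as it did the GTPase list (a share of 0.49). The median of the oxidant list was 0.95 in mouse 1717 against 0.79 and 0.91. Its gene-wise difference had a median of 0.11 against -0.43 needed, further than its interquartile range of 0.16, though its lower quartile was not above 0. By this rule, revised after outcomes were seen, the values argue against a weaker response scaled alike in both lists. The stricter rule tried before left it open. Fewer macrophages would have put their markers in the DSS library of mouse 1717 below the other DSS libraries, but the median difference was 0.30 (quartiles 0.18 and 0.55). One strength shared by interferon and cytokine genes stays open, since the cytokine median was 1.30 in mouse 1717 against 0.80 and 1.12 but the gene-wise median of 0.27 lay 0.76 above the -0.49 needed, within the interquartile range of 1.09, and a different interferon content of the medium or sensitivity of this animal's cells stays open as a hypothesis.

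Macrophage markers were lower in part. A lower share of macrophages alone would lower all of them by 1 common amount, but 14 of the 21 lay more than 2 SE from their median, 6 above and 8 below. This test replaced a first version, dropped because it left out genes picked for their fall. A change of state of these cells, with or without a change of their share, may be a candidate explanation and was not tested further.

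With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2639 called genes and the highest other 0 (edgeR), while the others counted 130 to 1475 genes at an unadjusted p under 0.05 against 5672, so 1 of 10 splits reached the real count. With the block, the real split gave 4965 (7359 at an unadjusted p under 0.05) and the 3 others that part all 3 mice gave 0 (71, 142 and 162). Each other split puts control and DSS libraries into the same group, so the difference of interest widens the spread within its groups and lowers its counts. For lists called by camera the real split gave 19 and the highest other 18, a split that parts 1 mouse, and 13 was the highest among those that part all 3, so 1 of 10 splits reached 19. Camera with a preset correlation called many lists in splits where edgeR called 0 genes. Each other split also keeps a part of the difference between control and DSS, so those calls need not be false. They cannot settle how reliable camera is here, and its list calls are to be read with the counts of genes beside them. With an estimated correlation camera called 0 lists in all 10 splits, with 3 at an unadjusted p under 0.05 in the real one and 0 to 1 in the others.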
